A study of Mus musculus with 3 samples.

How the data were processed

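Total RNA from mouse neural retina was compared on 3 two-colour microarrays, each hybridised with one RNA sample from cbs+/- mice and one from wild-type mice. Per the labels, the cbs+/- RNA carried Cy3 and the wild-type RNA carried Cy5 on all 3 arrays, and labelled cDNA was made with a commercial labelling kit after Trizol extraction. The series' design text speaks instead of reversed dyes and of 3 different pairs of RNA. The scanner, background correction, normalization, probe filters and array design are not given in the sources used here.

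The only file analysed holds the deposited log2 ratio of each probe on each array, which the authors made from the 2 channels. It has 38531 probes, 3 columns and 0 missing values, and it is read through the sample accession that heads each column. The base of the logarithm was taken as 2. With it, the ratios within each array cluster at steps of the log2 of 2 and of 3 below one constant, within 0.001 of rounding. Each constant was fitted to these same values. It was chosen for a high share of whole numbers among low ratios, then for the most probes at the constant itself. The constants were 0.701, 0.976 and 0.889 for replicates 1, 2 and 3, and 137, 178 and 47 probes lay at them, where the 2 channels have equal signals. Each array thus carries 1 additive constant, and an intensity-dependent (loess) step would not leave such steps. The table is not centred on 0: the medians were -0.46, -0.37 and -0.27, while the modes were 0.03, -0.01 and 0.00. The direction of the ratio is unknown. The titles name cbs+/- before wild type, which would put cbs+/- on top, while the habit of writing Cy5 over Cy3 would put wild type on top. Signs are therefore given as deposited, and no statement is made on which genotype had more RNA.

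A deposited value at least 5 log2 units from its array's constant was called a value with a channel set to 1 when 2 to the power of that distance was a whole number within rounding. A channel at 1 beside another that read less than 32 is therefore not counted, and tests that must include it use whole-number ratios at any distance, a choice made after the data were seen. The channel in the numerator is called the top channel and the one in the denominator the bottom channel. This reading is inferred from the numbers, since no source states a floor. Of the values at least 5 log2 units below the constant, 95.6%, 93.5% and 92.5% were whole on replicates 1, 2 and 3, against 21.4%, 24.2% and 21.8% by chance from the rounding. The chance figures do not allow for the fitting of the constants, which used some of these values. A top channel of 1 was far more frequent than one of 2: over odd bottom-channel readings from 65 to 127, the counts were 975 and 29 on replicate 1, 709 and 37 on replicate 2, and 498 and 27 on replicate 3. The size of such a ratio is not a measured fold.

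The test was fixed before the data were examined. Each array was centred on its median, and the mean log2 ratio of each probe over the 3 arrays was tested against 0 with limma 3.58.1 (lmFit with an intercept, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The labels call the arrays biological repeats. Nothing says how many mice gave each RNA, so p-values measure the spread between these 3 hybridisations. The number of arrays limits the precision. Probe identifiers in the table are internal numbers, and 0 of them matched the identifiers, symbols or accessions of the 49997 genes of the mouse RefSeq table used here (GRCm38.p6), so no probe could be named. For this reason the value of Cbs, the averaging of probes per gene, the 33 gene lists fixed beforehand (retinal cell types, stress pathways, methionine metabolism, lens, pigment epithelium, blood and others) and their set tests could not be evaluated and are not reported. Probes were named by the rule fixed for tables without gene names: the 2 most positive and the 2 most negative mean log2 ratios among probes past the threshold with the same sign on all 3 arrays.

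Alternatives named in advance were no centring, scaling of the arrays to one median absolute deviation, leaving out the most variable 10% of probes, robust eBayes, array weights, turning the sign of each array, leaving out each array, an unmoderated test per probe and other thresholds. Chosen after the data were seen were leaving out probes with a channel set to 1 on any array (centred or as deposited), leaving out probes 3 or more log2 units from the constant, centring on probes with no channel set to 1, leaving out a separate block of identifiers, and subtracting a running median over 501 neighbouring identifiers.

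The fit was tested on simulated arrays with variances drawn from its own fitted prior. With 200 of 38531 probes changed, 50 at each size, it called 0 of 50 at a log2 change of 1, 0 of 50 at 2, 0 of 50 at 4 and 0 of 50 at 6. On the 30156 probes with no channel set to 1, it called 0 of 50 at 1, 3 of 50 at 2, 34 of 50 at 4 and 42 of 50 at 6, and 7 of 29956 unchanged probes. When 1171 of 38531 probes were changed together by -6, with the spread of the probes set to 1 on 3 arrays, it called 1143 of them and 54 unchanged probes. With no probe changed it called 0 in both simulations. Absence of a call in the test of all 38531 probes therefore says little about isolated changes of any of these sizes. In the 30156 probes it says little about changes of 1 or 2 log2 units. Larger changes that leave a channel at 1 are outside the 30156 probes by construction. The simulations of isolated changes altered 200 probes, whereas 9187 of the 30156 real probes had an unadjusted limma p under 0.05.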

Results

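Cystathionine beta-synthase, encoded by Cbs, condenses homocysteine with serine, and mice that carry one inactivated copy serve as a model of raised homocysteine. Gene expression was compared between neural retinas of cbs+/- mice of the B6.129P2-Cbstm1Unc/J strain and wild-type C57BL/6 mice, on 3 two-colour arrays. Both genotypes drank water with 0.5% methionine, the precursor of homocysteine, from weaning, and the labels give 5 weeks both as the time of treatment and as the age. The array titles, however, put HM beside cbs+/- only and not beside wild type. If the treatment differed between the genotypes, its effect could not be told apart from that of genotype. The comparison addresses which retinal transcripts differ between the genotypes under this methionine load. The probes carry no gene names here, so Cbs itself and its pathway were not analysed, and results are given by probe. Ratios keep their deposited sign. Which genotype lies in the numerator (top channel) is not settled by the labels.

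The 3 arrays shared a strongly one-sided distribution of ratios. Of 38531 probes, 68.9%, 66.7% and 64.1% had a negative log2 ratio on replicates 1, 2 and 3, with medians of -0.46, -0.37 and -0.27. The most frequent ratio on each array nevertheless lay near 0, at 0.03, -0.01 and 0.00. Ratios reached from -9.22 to 10.78 on replicate 1, from -9.44 to 9.38 on replicate 2 and from -9.23 to 7.58 on replicate 3, and each array had a second, smaller peak far below 0.

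**Figure D1:**
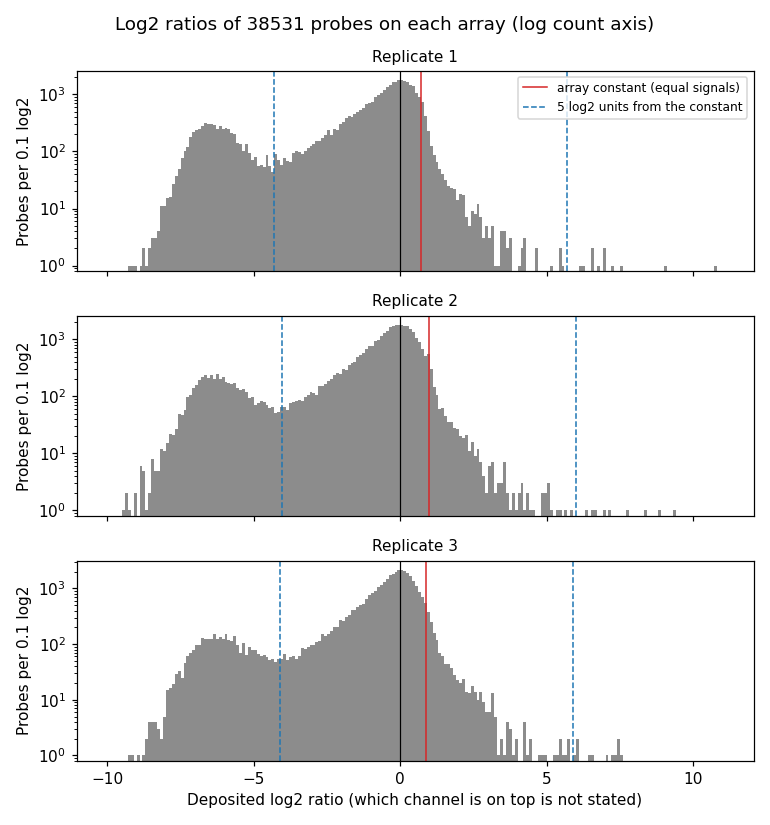
Number of probes (log axis, bins of 0.1 log2 units) by deposited log2 ratio for replicates 1 to 3. The red line marks the value at which both channels have equal raw signals (0.701, 0.976 and 0.889), and the dashed lines lie 5 log2 units from it. The main peak is near 0 on every array, and the second peak lies left of the lower dashed line.

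The second peak consisted of probes whose top-channel signal equalled 1 in the units of the other channel, as read from the whole-number steps of the ratios. There were 5436 such probes on replicate 1 (14.1% of all), 4559 on replicate 2 (11.8%) and 2972 on replicate 3 (7.71%). The bottom channel was at 1 on only 11, 9 and 10 probes. A channel was counted as at 1 only where the other read at least 32, so these counts leave out dimmer probes. Where the top channel was at 1, the bottom channel read a median of 132 (quartiles 92 and 182) on replicate 1, 148 (97.5 and 209) on replicate 2 and 129 (84 and 192) on replicate 3. The same probes recurred: the top channel was at 1 on all 3 arrays for 1171 probes, where 49.6 would be expected if the arrays were independent. In these 1171 probes the log2 ratios, which there depend on the bottom channel alone, correlated between arrays across probes with Pearson r from 0.62 to 0.67. Probes are not independent replicates, so no p-value is attached to a correlation across them.

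Arrays resembled each other in the remaining probes too. Across all probes, Pearson r was 0.52 between replicates 1 and 2, 0.52 between 1 and 3 and 0.48 between 2 and 3, with Spearman rho of 0.57, 0.59 and 0.53. In the 30156 probes with no channel at 1 on any array, r was 0.42, 0.45 and 0.41, and rho was 0.51, 0.56 and 0.50. After each array was centred on the median of these probes, 56.9% of them had the same sign on all 3 arrays, against 25% by chance. The standard deviation over the 3 arrays had a median of 0.36 log2 units in these probes (quartiles 0.20 and 0.69). It was 2.90 (2.18 and 3.36) in the 8375 probes with a channel at 1 on at least 1 array. In the 1171 of them with the top channel at 1 on all 3 arrays it was only 0.32 (0.19 and 0.52). There the ratio varies with the bottom channel alone.

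**Figure D2:**
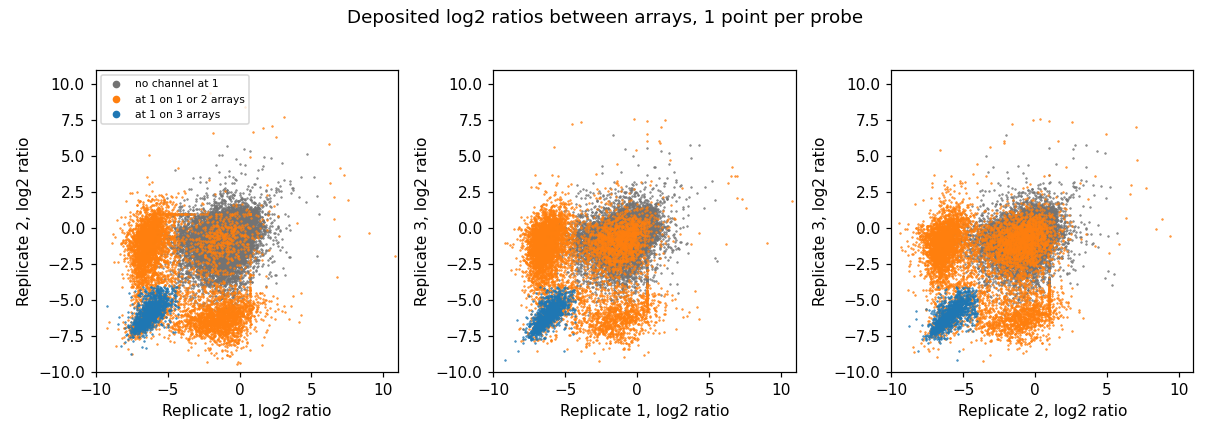
Deposited log2 ratio of each probe on 1 array against another, for the 3 pairs of arrays. Blue points had a channel at 1 on all 3 arrays, orange points on 1 or 2 arrays, and grey points (30156 probes) on none. The grey cloud slopes upward in each pair (Pearson r of 0.42, 0.45 and 0.41), and the blue points cluster at the lower left.

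Tested over the 3 arrays, 1355 probes (3.52%) had a mean log2 ratio different from 0 at an adjusted p of 0.05 (limma, Benjamini-Hochberg over 38531 probes). Of these, 1314 were negative, with means from -7.96 to -1.63 and a median of -5.64. The other 41 were positive, with means from 1.53 to 3.50 and a median of 2.02. The split was 1419 negative and 21 positive with the values as deposited and not centred. Leaving out 1 array brought the calls close to the threshold: limma called 0 probes without replicate 1, 1289 without replicate 2 and 1941 without replicate 3, with lowest adjusted p-values of 0.056, 0.046 and 0.038. Without replicate 1 the ratios of the called probes were as large, which their selection over all 3 arrays largely ensured. The median was -5.61 over the 1314 negative and 2.00 over the 41 positive probes. In that fit, 5790 of all probes had an unadjusted limma p under 0.05. Turning the sign of replicate 1, 2 or 3 also left limma with 0 calls, and with 266, 411 and 355 probes under an unadjusted 0.05.

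The negative calls were mostly probes with no measurable top channel. The top channel was at 1 on all 3 arrays in 1146 of the 1314, on 2 arrays in 113 and on 1 array in 13, and 42 had no channel counted as at 1. The as-deposited means of these 42 had a median of -2.78. A top channel at 1 there would pair with a bottom channel too dim to be counted. Whole numbers at any distance from the constant were not counted for these 42. Of the 37176 probes not called, 5.90% had a channel at 1 on 2 or 3 arrays. None of the 41 positive calls had a channel counted as at 1, and 3 of their 123 values gave a whole number at any distance from the constant. The most negative mean among the calls was that of probe 1793961_1, at -7.96 ± 0.28 (SD, n = 3; limma adjusted p = 0.0041), followed by probe 1790721_1 at -7.48 ± 0.05 (SD, n = 3; limma adjusted p = 0.0041). In both, the top channel was at 1 on all 3 arrays, so these values are not measured folds. The bottom channel read 499, 568 and 696 for probe 1793961_1 and 405, 468 and 384 for probe 1790721_1. The most positive means among the calls were those of probe 1782885_1, at 3.50 ± 0.24 (SD, n = 3; limma adjusted p = 0.0093), and probe 1718929_1, at 3.49 ± 0.60 (SD, n = 3; limma adjusted p = 0.035). Probe 1718929_1 belongs to a separate block of 64 identifiers at the head of the table.

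**Figure D3:**
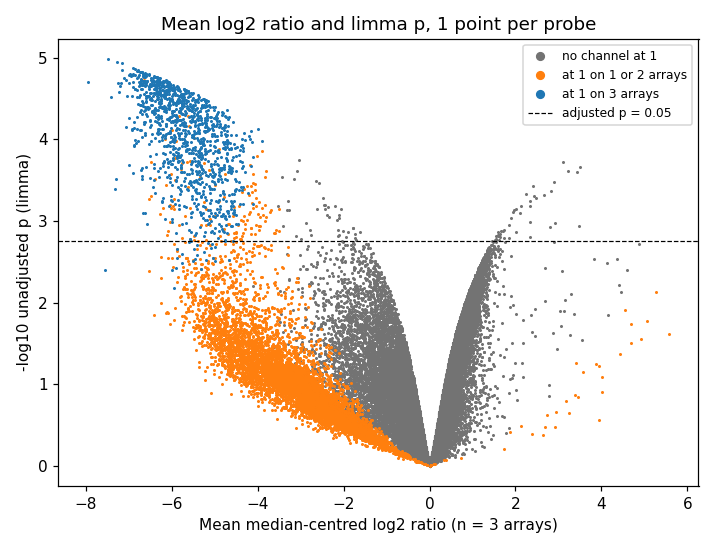
Mean median-centred log2 ratio of each probe over 3 arrays against -log10 of its unadjusted limma p. The dashed line marks an adjusted p of 0.05, and colours show on how many arrays a channel was at 1. Above the line are 1314 negative and 41 positive probes, and 1146 of the negative ones are blue.

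When the 8375 probes with a channel at 1 on any array were left out, a setting chosen after the data were seen, limma called 0 of the 30156 that remained, with a lowest adjusted p of 0.094. An unmoderated test of each probe also called 0. Small unadjusted p-values were nevertheless frequent: 9187 of the 30156 probes (30.5%) had a limma p under 0.05, 4705 of them positive and 4482 negative, and the unmoderated test gave 6639. The even split came with the centring on these probes: with their values as deposited, 2713 were positive and 6309 negative, of 9022. At an adjusted p of 0.1, limma called 2847 of the centred probes, of which 1482 were positive and 1365 negative, and 0 with the values as deposited (lowest adjusted p 0.10). After centring, a probe with equal raw signals in both channels lies above 0. The array constants of 0.701, 0.976 and 0.889 exceed the medians. How many of the 1482 are such probes was not counted. For the 83 probes called before the exclusion that had no channel at 1, only the new centring could change the mean. Their median absolute mean was 2.24 before and 2.29 after the exclusion, with a median SD of 0.20. The median of their unadjusted limma p-values was 0.00097 before and 0.00025 after it. The adjusted p of each nevertheless rose to 0.094 in limma, because the adjustment no longer included the very small values of the probes at 1.

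By size alone, 4106 of the 30156 probes (13.6%) differed at least 1.5-fold the same way on each of the 3 arrays. Each array was centred here on the median of these probes, and 1655 were positive and 2451 negative. With the values as deposited and not centred, the split was 845 positive and 3517 negative. Turning the sign of replicate 1, 2 or 3 reduced the 4106 centred probes to 234, 322 and 241. A probe with equal raw signals in both channels on all 3 arrays counts as positive, centred or as deposited. The array constants of 0.701, 0.976 and 0.889 exceed a 1.5-fold ratio, and centring raised them. How many of the positive probes lie there was not counted.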

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

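Alternatives that left out probes by their channel signal or their identifier, recentred on them or subtracted a running median were chosen after the data were seen. With sign of array 1 turned, sign of array 2 turned or sign of array 3 turned, and with probes with a channel set to 1 left out (centred or as deposited) or those 3 or more log2 units from the constant left out, the counts of all, positive and negative calls were each 0. Leaving out 1 array gave 0 to 1941 calls, of which 0 to 2 were positive and 0 to 1939 negative; the lowest adjusted p without replicate 1 was 0.056. The 41 positive calls became 21 without centring, 23 with arrays scaled to one spread, 27 with centring on probes with no channel set to 1, 482 without the most variable 10% of probes (2084 in all) and 406 with the unmoderated test, which gave 714 negative calls. Looser thresholds raised the counts: an adjusted p of 0.1 gave 2943 calls, 1069 positive (79 positive as deposited, 228 centred on probes with no channel set to 1); 0.2 gave 13594, with 7304 positive and 6290 negative; and an unadjusted p of 0.05 with at least 1.5-fold gave 10417, with 5495 positive and 4922 negative. Beyond the construction of these settings, the cause was not tested. Robust eBayes, array weights, leaving out the block of 64 identifiers, the running median, and a 1.5-fold minimum kept each count within 1.5 times. Of the 1355 calls, 1333 were shared with the values as deposited and 1310 with the running median, but 859 with the 1289 calls without replicate 2, 907 with the 1941 without replicate 3 and 706 with the 1120 of the unmoderated test. The 4 named probes kept their sign in every setting that held them, which their naming by size and by the same sign on all 3 arrays largely ensured. They were past the threshold in 37 and short of it in 27 of the combinations of probe and setting. Filters on missing values change nothing in a complete table, and rules on probes per gene, Cbs and gene lists could not be run without gene names. The test of the log2 ratio already compares the 2 RNA samples of each pair within their array, so no further paired analysis was run.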

Other observations

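The tests of whole numbers (in negative calls, positive calls and the block of identifiers), of negative calls along identifier order, channels set to 1 in the correlations, genotype and dye were chosen after the results they bear on were seen. The sign turns, as alternative settings, and the running median in the correlations were named before their results were seen. The use of the sign turns as a test of chance was written down only afterwards. Turning signs leaves 4 distinct sign patterns of the 3 arrays. The real pattern gave 1355 calls and the highest of the other patterns gave 0, so 1 of the 4 splits gave as many. These are too few for a share under 0.05.

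For the excess of negative calls, 1314 of 1355, a candidate explanation is that background subtraction left the top channel at or below 0 and that it was then set to 1: of the 1967 values of negative calls that lay 5 to 7 log2 units below the constant, 96.9% gave a whole number for the bottom channel, against 12.5% by chance. This may account for the size of these ratios, but not for which probes were dark. The constants were fitted on low ratios in an overlapping range, which the chance figure does not allow for. The share of probes with the top channel at 1 on all 3 arrays varied along identifier order, from 0.27% to 4.99% over 26 bins, but a trend along that order as the whole cause is argued against by the shares within bins of 100 neighbouring identifiers, which predict 78.8 such probes where 1171 were observed. A difference in RNA level between cbs+/- HM and wild-type retina cannot be told apart from a weaker or more heavily background-corrected dye, because the labels put one genotype in one dye on every array and the top channel was the darker one on all 3 arrays. For the 41 positive calls, a bottom channel set to 1 as the whole cause is argued against. Such a channel would give a whole number for the top channel however dim that was, and of their 123 values 3 gave one, with 0% of the probes doing so on 2 or 3 arrays. Of the 26 values 5 to 7 log2 units above the constant on all arrays, 96.2% were whole, against 10.3% by chance.

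The second pattern is the positive correlation between arrays. Probes with a channel at 1 do not account for it, since the lowest Pearson r between arrays was still 0.41 in the 30156 probes without one, and 0.42 in the 28944 probes with no whole-number ratio at any distance from the constant. A smooth identifier-order trend as the whole cause is argued against in the 30156 probes, where the lowest r was 0.40 after the running median. Among the explanations left open are a dye effect shared by arrays of one orientation and a genotype difference. The lowest r over all probes with signs as deposited was 0.48, which does not separate them. Other probe properties shared by the arrays were not tested. If any array had reversed dyes, as the design text implies and the labels do not, and ratios were turned to one direction, a pure dye effect might have given a negative correlation with that array. None was seen, but neither premise could be checked here.

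The third pattern is a block of 64 probes whose identifiers lie apart from the rest. Their median log2 ratios were 2.22, 2.80 and 2.84 on replicates 1, 2 and 3, against -0.46, -0.38 and -0.27 in the other 38467 probes, and 43 of the 64 (67.2%) were positive on all 3 arrays, against 16.2% of the others. A positive sign on all 3 arrays was not particular to the block. Most probes in the run of identifiers directly after it shared that sign, with smaller ratios that lay mostly near the array constants. That run is pooled with the others here and was not tested separately. The bottom channel was at 1 on at least 1 array in 19 of the 64 and in 10 of the 38467. These counts leave out a bottom channel at 1 under a top channel that read less than 32. Counted at any distance from the constant, 46 of the block's 163 values not below it were whole, where 3.22 would be expected by chance, and 40 of the 64 probes had at least 1. A bottom channel set to 1 may therefore account for part of the block, but 6 of the 64 had a whole number on 2 or 3 arrays, which argues against it as the whole cause. Control spots are a possible explanation that could not be tested without probe annotation, and 7 of the 41 positive calls lie in this block.

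The share of probes with the top channel at 1 varied along the identifier order. On replicate 1 it was 3.92% in the first of 26 equal bins and 25.9% in bin 25, and on replicate 3 it was 1.76% and 15.1% in the same bins.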
